A study of Mus musculus with 19 samples.

How the data were processed

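Total RNA from mouse hippocampus was depleted of cytoplasmic and mitochondrial ribosomal RNA and sequenced, per the labels' protocols. The tissue was taken 4 days after kainate or saline, flash frozen and stored until all samples were in hand, per the labels' protocols. The 19 libraries fall into 4 groups of 2 genotypes and 2 treatments. The titles number the 4 EZH2nHom kainate libraries from 1 to 4 while their columns are numbered from 2 to 5, and the title numbers are used throughout.

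The main input was a deposited table of whole-number read counts per Ensembl gene for 55416 genes, of which 32474 had a read in any library. The submitters' processing notes name the genome build mm39, DESeq2 and DESeq without versions, and state no aligner, counting program, annotation release or strand setting. A second deposited table holds normalised signal, the counts divided by 1 size factor per library by the authors, for 32427 genes. That table also holds log2 fold changes with their errors, a test score, p-values and adjusted p-values, per the file headers. The deposited log2 fold change matched the ratio of WT saline to EZH2nHom kainate. Of 23334 genes with an adjusted p-value from the authors, 9451 were under 0.05, but the file does not state which comparison these p-values test. Another deposited table, of 6240 genes, holds the same normalised signal, and 328 of its genes had an adjusted p-value of 0.05 or more. These tables were used for gene names and to identify units, and every test below was computed from the read counts. Symbols came from the authors' table for 32313 genes and from a reference table of gene names for 20022, and 3081 had none.

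Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15. Genes were kept by filterByExpr by group, which left 19234. TMM factors scaled the libraries. A quasi-likelihood model with robust estimation and a mean per group was fitted to all 19 libraries, so that the groups shared 1 estimate of the spread. The 5 contrasts were kainate against saline in each genotype, EZH2nHom against WT after each treatment, and the difference of the kainate responses. Tests were two-sided with Benjamini-Hochberg adjustment over all genes, and a gene passed at an adjusted p under 0.05. Changes are given as log2 fold changes ± SE, and levels as CPM, read counts scaled to the library total times its TMM factor, ± SD. Total reads ran from 24496685 to 43948317 per library, and the median SE of a log2 change was 0.12, 0.128, 0.12, 0.128 and 0.175 in the 5 contrasts. A floor of 3 reads per library bounded folds against groups without reads. Such floors cover counting error only.

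The following were fixed before the data were examined: the groups, tests, gene lists, rule for named genes and the first set of alternatives listed below. The rule named Ezh2 and, in each contrast, the 10 largest rises and 10 largest falls (5 and 5 for the difference of responses). Eligible genes passed the test, averaged at least 1 CPM, had no overlap in CPM between the groups compared (not asked of the difference of responses) and had a named symbol. Up to 4 members with the smallest p per list described were added. Gfap, Vim, C4b, Calb1 and the other list members quoted come from this part of the rule. The 41 gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a contrast. Members were also adjusted over the list alone. The overlap of the kainate responses was set against independent lists of the same sizes. The size of the response was the median difference over genes that passed for the average response. It was planned with random resamples, and all 31752 relabellings of genotype within treatment were enumerated instead, which makes the test exact.

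Same-numbered WT libraries deviated together from their group means (correlations of 0.221 to 0.571 in 5 pairs, 3 of 5 libraries matching best with their own number), so a pairing by number was tried. The pairing comes from the data and not from a statement in the labels, and the main fit did not use it. Code prefixes go with it for replicate 2 (081321 in both arms), but WT saline replicate 4 shares its prefix (070721) with WT kainate replicate 1. Xist was read and Y-linked genes were at or near 0 in replicates 1 and 2 of both arms, so the numbers also part the libraries by sex-linked reads. With the replicate number as a block the WT kainate response had 2477 genes against 2316 without it. Sample code prefixes, whose meaning the labels do not give, occur in both WT arms for 6 libraries, and 0 occur in both genotypes.

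Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter and a stricter filter on low counts, a fit to only the groups compared, the replicate block, a covariate from Y-linked genes, the shared code prefixes, a stricter threshold and leaving out each library. The share of structural RNA reads as a covariate, a correction for GC content and transcript length, and the size test in libraries with Y-linked reads were chosen after seeing the data. An annotation of mm39 was not used here. GENCODE release M21, of another build, was used only for GC content, length, the order of genes and sequence shared between gene models. A gene was taken to share sequence where exonic bases overlapped another gene or at least 20% of its 32-base words occurred in another gene model.

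The tests were checked on simulated counts with the real means and library sizes, in which 88, 66 and 66 genes were changed by 1.5, 2 and 4-fold in each contrast. Recovery was 50%, 69.7% and 97% for the WT kainate response (18931 genes), 43.2%, 68.2% and 95.5% for the EZH2nHom kainate response (18983 genes), 47.7%, 77.3% and 97% for genotype after saline (18964 genes), and 46.6%, 78.8% and 93.9% for genotype after kainate (18969 genes). It was 14.8%, 65.2% and 87.9% for the difference of responses (18976 genes), and 6 to 8 unchanged genes were called per contrast. A planted GC trend gave 1991 false calls before the correction and 0 after it (18947 genes). No library was left out, and no pair of libraries was a duplicate.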

Results

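RNA was sequenced from mouse hippocampus 4 days after status epilepticus, a prolonged seizure induced with repeated low doses of the glutamate receptor agonist kainate, or 4 days after saline. The mice either kept EZH2, the methyltransferase of the Polycomb repressive complex PRC2, and carried the neuronal Synapsin1-Cre driver (WT), or carried the driver with floxed EZH2 alleles for deletion in neurons (EZH2nHom). There were 5 WT saline, 5 WT kainate, 5 EZH2nHom saline and 4 EZH2nHom kainate libraries, 19 in all. Total reads per library ran from 26607591 to 33649565 in WT saline and from 24496685 to 38436154 in WT kainate. They ran from 26114855 to 41404459 in EZH2nHom saline and from 29778706 to 43948317 in EZH2nHom kainate. The leading principal component of log2 CPM held 39.4% of the variance and placed all 10 saline libraries between -47.1 and -38.3 and the 9 kainate libraries between -2.8 and 85.2. The next component held 13.9% and set EZH2nHom kainate replicate 2, at -108.5, apart from the other 18 libraries, which lay between -19 and 27.5. Xist was read and Y-linked genes were at or near 0 in 2 of 5 WT saline, 2 of 5 WT kainate, 0 of 5 EZH2nHom saline and 1 of 4 EZH2nHom kainate libraries.

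Ezh2 was the targeted gene (ENSMUSG00000029687), and its gene-level count was not lower in the knockout libraries. After saline, Ezh2 averaged 11.25 ± 1.17 CPM (SD, n = 5) in WT and 13.59 ± 1.42 CPM (SD, n = 5) in EZH2nHom, and 6 of the 252 relabellings gave a difference as large (exact two-sided permutation p = 0.0238). After kainate it averaged 15.16 ± 4.53 CPM (SD, n = 5) in WT and 17.54 ± 2.39 CPM (SD, n = 4) in EZH2nHom (exact two-sided permutation p = 0.389). In the edgeR model the genotype log2 differences for Ezh2 were 0.27 ± 0.16 (SE, adjusted p = 0.288) after saline and 0.21 ± 0.17 (adjusted p = 0.473) after kainate, and neither passed. Kainate gave Ezh2 log2 changes of 0.43 ± 0.16 in WT (adjusted p = 0.0906) and 0.37 ± 0.17 in EZH2nHom (adjusted p = 0.112), which did not pass either. The counts cover the whole gene and all cells of the tissue, glia included, so they did not check the genotype labels.

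Kainate in WT mice was compared with saline in WT mice, which asks what status epilepticus did to the hippocampus when neuronal EZH2 was present. Gfap, the intermediate filament of reactive astrocytes, rose by 3.27 ± 0.20 on the log2 scale (SE, adjusted p under edgeR = 1.87e-08), Vim by 3.81 ± 0.34 and the complement gene C4b by 3.25 ± 0.27. Cst7, a cysteine protease inhibitor of activated microglia, went from 0.0693 ± 0.0413 CPM to 9.32 ± 9.59 CPM (SD, n = 5 each, adjusted p = 0.000107). Tgm1, a transglutaminase, went from 0.056 ± 0.0402 to 43.7 ± 55.7 CPM (adjusted p = 0.000294). The calcium-binding protein gene Calb1, a marker of dentate granule cells, fell by 1.03 ± 0.14.

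Of 19234 genes tested, 2316 passed in WT, 1821 higher and 495 lower after kainate, of which 1075 rose and 96 fell by 2-fold or more. The other largest rises by the rule fixed for named genes were Apoc2, Hcar2, Timp1 (6.52 ± 0.84), Cd5l, Cd244a, Cd72 (6.02 ± 0.94), Fcgr4 and Ifi209 (5.43 ± 0.78). Fold changes are not given for Apoc2, Hcar2, Cd5l, Cd244a and Fcgr4, which had 2, 3, 5, 4 and 14 reads over all 5 WT saline libraries. The largest falls were Rtl3, a retrotransposon-derived gene (-2.24 ± 0.39), Slc26a10 (-1.96 ± 0.47), Gmnc (-1.93 ± 0.46), the neuropeptide gene Cort (-1.76 ± 0.39), Kirrel2 (-1.76 ± 0.17), and Tdo2 (-1.69 ± 0.39). Next came the desmosome gene Dsp (-1.50 ± 0.34), the potassium channel gene Kcng3 (-1.35 ± 0.19), Ryr1 (-1.25 ± 0.23) and the neurotrophin gene Ntf3 (-1.23 ± 0.17).

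Among the gene lists, 19 were higher and 6 lower in WT after kainate by camera with a preset correlation, and 0 passed with a correlation estimated from the data, where the smallest adjusted p was 0.083. All 31 measured type I interferon genes rose, as did 31 of them adjusted over the list alone, with Gbp2 at 2.92 ± 0.40 and Rsad2 at 2.49 ± 0.38 (list adjusted p = 5.2e-36, or adjusted p = 0.086 with an estimated correlation). Of 37 reactive astrocyte genes 29 rose, 0 fell and 8 did not pass (32 rose adjusted over the list alone; adjusted p = 0.083 with an estimated correlation). Of 30 activated microglia genes 27 rose and 3 did not pass (28 adjusted over the list alone; adjusted p = 0.086 with an estimated correlation), with Clec7a at 4.12 ± 0.46. Of 20 homeostatic microglia genes 19 rose (20 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation), with Ctss at 2.14 ± 0.23. Complement had 16 of 20 genes higher (16 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation). Antigen presentation had 18 of 21 higher (20 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with H2-D1 at 2.46 ± 0.30. JAK-STAT signalling had 21 of 40 higher (25 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Of 34 proliferation genes 31 rose and 3 did not pass (32 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation), with Mki67 at 3.02 ± 0.38.

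Of 15 dentate granule cell genes 6 fell and 9 did not pass (6 fell adjusted over the list alone; adjusted p = 1.3e-06, or adjusted p = 0.11 with an estimated correlation). Of 22 inhibitory neuron genes 7 fell, 1 rose and 14 did not pass (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.083 with an estimated correlation). Adarb2 fell by 0.94 ± 0.12, and the neuropeptide gene Npy was the member that rose (1.72 ± 0.28). Of 12 genes of CA1 pyramidal cells 0 passed in edgeR, and the list was not called (0 adjusted over the list alone; adjusted p = 0.17, or adjusted p = 0.65 with an estimated correlation). Of 17 genes of CA3 and CA2 pyramidal cells 1 fell, and this list was not called either (1 adjusted over the list alone, adjusted p = 0.059, or adjusted p = 0.37 with an estimated correlation). It was called lower by camera without WT saline replicate 2, WT kainate replicate 1 or WT kainate replicate 5 (adjusted p = 0.0252, 0.0322 and 0.0134). Of 36 glutamate and GABA receptor genes 5 fell and 31 did not pass (6 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). Of 7 red blood cell genes 6 rose (7 adjusted over the list alone, adjusted p = 0.3 with an estimated correlation), with Hbb-bt at 1.92 ± 0.54. The mean log2 CPM of these genes was 6.36 and 5.87 in WT kainate replicates 1 and 3. In the other WT kainate libraries it was 4.1 to 4.48, inside the WT saline range of 2.85 to 4.53. PRC2 and its partners were not called as a list: of 13 genes Phf19 rose (1.58 ± 0.39) and 12 did not pass (1 rose adjusted over the list alone; adjusted p = 0.66 with an estimated correlation). The list of developmental factors that Polycomb commonly silences holds 91 genes, of which 15 passed the filter on low counts and were measured. The rest were not tested, so the list does not speak for them. Of the 15, Nkx2-2 (1.35 ± 0.37) and the pro-apoptotic gene Bcl2l11 (0.57 ± 0.16) rose while 13 did not pass (2 rose adjusted over the list alone, adjusted p = 0.92 with an estimated correlation). Genes were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The count fell to 933 with the share of structural RNA reads as a covariate, and to 1401, 1365 and 1518 without WT kainate replicate 3, WT kainate replicate 4 or WT saline replicate 2. It fell to 0 in the 6 libraries whose sample code prefixes occur in both WT arms, with the prefix as a block. There 2167 genes had an unadjusted p under 0.05. These libraries, WT saline replicates 2 and 4 and WT kainate replicates 1 to 4, leave little power.

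**Figure D1:**
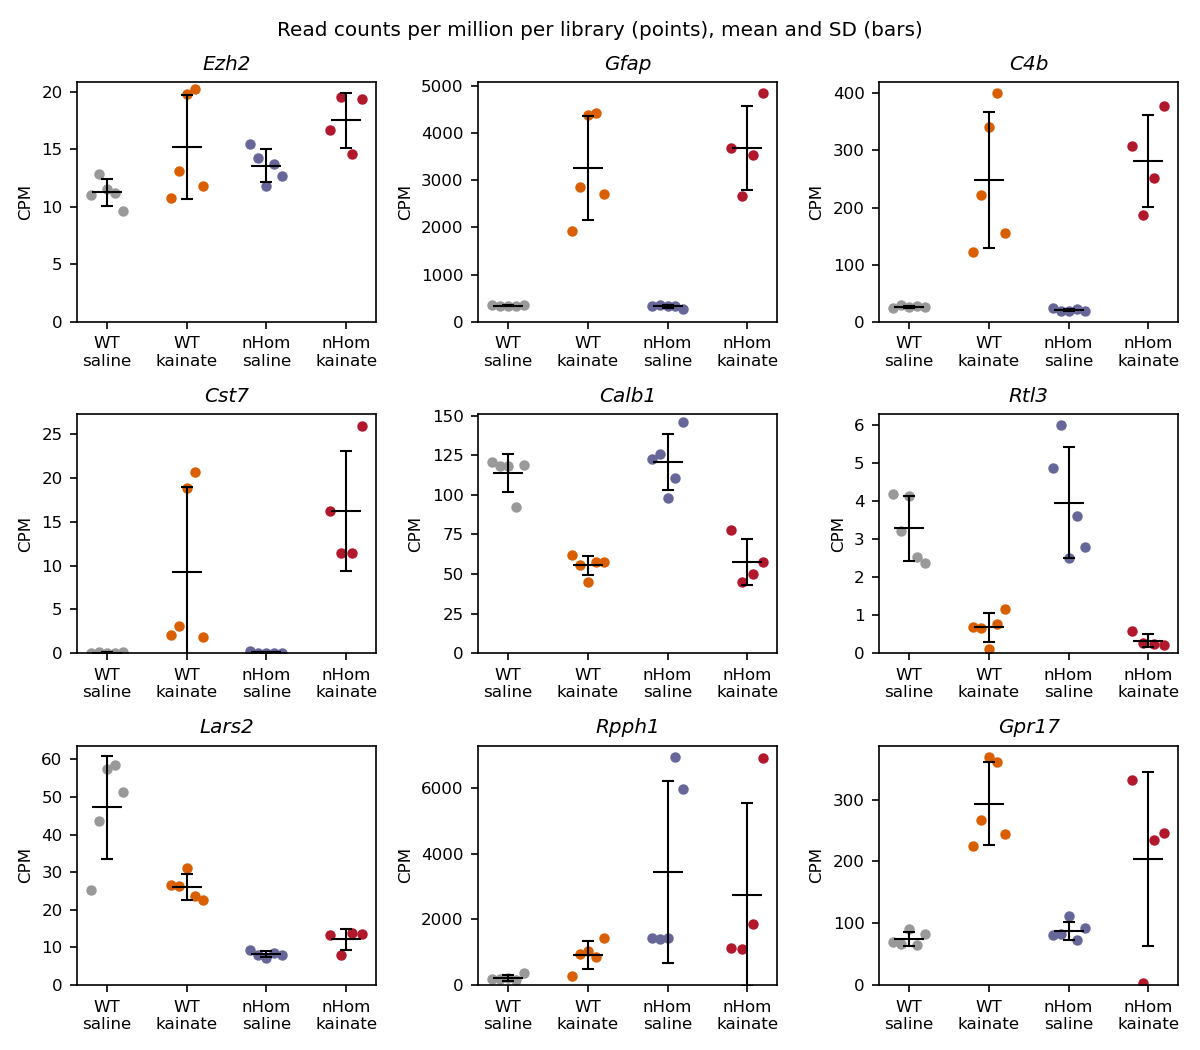
CPM (read counts scaled to library size) by library for 9 genes in the 4 groups; points are libraries, horizontal bars are group means and error bars are 1 SD. Gfap, C4b and Cst7 were higher and Calb1 and Rtl3 lower after kainate in both genotypes, Lars2 was lower and Rpph1 higher in EZH2nHom after saline, and Gpr17, chosen after its values were seen, was at 2.8 CPM in EZH2nHom kainate replicate 2.

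The same comparison in EZH2nHom mice asks what status epilepticus did to a hippocampus whose neurons were to lack EZH2. Gfap rose by 3.51 ± 0.21 on the log2 scale (SE, adjusted p under edgeR = 9.57e-09), Vim by 4.52 ± 0.36, C4b by 3.76 ± 0.28 and the metalloproteinase inhibitor gene Timp1 by 7.61 ± 0.84. Cst7 went from 0.1 ± 0.102 CPM (SD, n = 5) to 16.2 ± 6.84 CPM (SD, n = 4, adjusted p = 1.87e-05) and Tgm1 from 0.0467 ± 0.0442 to 49.1 ± 31.3 CPM (adjusted p = 9.62e-05). Calb1 fell by 1.07 ± 0.14 and Rtl3 by 3.52 ± 0.46.

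In EZH2nHom 5012 genes passed, 2746 higher and 2266 lower after kainate, of which 1558 rose and 311 fell by 2-fold or more. The other largest rises were Saa3, an acute-phase gene, Cd5l, Apoc2, the iron-scavenging lipocalin gene Lcn2 (7.59 ± 1.49), the chemokine gene Ccl2, Ifi206 and Cd72 (7.15 ± 0.98). Saa3 was at 32.7 CPM in EZH2nHom kainate replicate 2 and between 0.21 and 1.32 CPM in the other 3 kainate libraries, and Saa3, Cd5l, Apoc2, Ccl2 and Ifi206 had 1, 3, 2, 6 and 2 reads over the 5 saline libraries. Most of the sequence of Apoc2 (88.5% of its 32-base words) and part of that of Ifi206 (29.6%) occurs in other gene models, so their counts are uncertain. The largest falls after Rtl3 were Cort (-2.70 ± 0.44), Irs4 (-2.53 ± 0.68), Baiap3 (-2.23 ± 0.54), Vwa5b1 (-2.15 ± 0.48), Otof (-2.03 ± 0.61), the neuroglobin gene Ngb (-2.02 ± 0.40), Sp8 (-1.93 ± 0.61), Ankrd63 (-1.87 ± 0.38) and Ano2 (-1.75 ± 0.41). In EZH2nHom saline Otof (8.74 ± 10.71 CPM, SD), Baiap3 (16.91 ± 14.38) and Irs4 (2.02 ± 1.82) varied widely between libraries. Irs4 was at 5.17 CPM in EZH2nHom saline replicate 5 and between 0.73 and 1.95 CPM in its group mates.

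By camera with a preset correlation 17 lists were higher and 11 lower in EZH2nHom after kainate, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.073. All 31 type I interferon genes rose (31 adjusted over the list alone; adjusted p = 0.073 with an estimated correlation), with Gbp2 at 4.02 ± 0.42. Of 37 reactive astrocyte genes 34 rose, 1 fell and 2 did not pass (35 rose and 1 fell adjusted over the list alone; adjusted p = 0.073 with an estimated correlation). Of 30 activated microglia genes 28 rose (28 rose and 1 fell adjusted over the list alone; adjusted p = 0.073 with an estimated correlation), with Clec7a at 5.12 ± 0.48. Of 34 proliferation genes 32 rose (33 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation). Antigen presentation had 20 of 21 genes higher (21 adjusted over the list alone; adjusted p = 0.073 with an estimated correlation) and apoptosis and the p53 response 14 of 22 (14 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation). Of 30 immediate early genes 12 rose, 1 fell and 17 did not pass (13 rose and 2 fell adjusted over the list alone, adjusted p = 0.39 with an estimated correlation), with Nptx2 at 1.61 ± 0.27, and this list was not called without EZH2nHom kainate replicate 2 or 3 (adjusted p = 0.0655 and 0.061). Its mean log2 change was 0.53 and 0.658 without these libraries and 0.693 with all. Of 40 cytosolic ribosomal protein genes 22 rose and 18 did not pass (26 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation).

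Of 22 inhibitory neuron genes 16 fell, 1 rose and 5 did not pass (18 fell and 1 rose adjusted over the list alone; adjusted p = 0.073 with an estimated correlation), with Npy at 1.85 ± 0.29. Of 36 glutamate and GABA receptor genes 19 fell and 17 did not pass (23 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), with the receptor genes Grm5 at -0.60 ± 0.10 and Gria2 at -0.62 ± 0.11. Of 17 genes of CA3 and CA2 pyramidal cells 6 fell (6 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with Pcp4 at -0.80 ± 0.09. Of 12 genes of CA1 pyramidal cells 4 fell (4 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). Of 15 dentate granule cell genes 5 fell (5 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Of 22 oligodendrocyte and myelin genes 6 fell, 2 rose and 14 did not pass (9 fell and 2 rose adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), with Mal at -0.94 ± 0.22 and Mobp at -0.73 ± 0.18. The mean log2 CPM of this list was 5.38 in EZH2nHom kainate replicate 2 against 6.24 to 6.87 in its group mates, and without that library the list was not called (mean log2 change -0.18, adjusted p = 0.236). Of 24 cholesterol synthesis genes 9 fell (11 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation), with Idi1 at -0.73 ± 0.14. None of the 7 red blood cell genes passed (0 adjusted over the list alone; adjusted p = 0.9 with an estimated correlation). Of the PRC2 list Phf19 rose (1.77 ± 0.40), Ezh1 fell (-0.43 ± 0.11) and 11 did not pass (3 rose and 3 fell adjusted over the list alone; adjusted p = 0.89 with an estimated correlation). Of the 15 measured Polycomb-silenced factors 3 rose, among them Pax5 and Bcl2l11 (0.66 ± 0.17), 2 fell and 10 did not pass (4 rose and 3 fell adjusted over the list alone; adjusted p = 0.86 with an estimated correlation). Genes were tested with the same edgeR test. The count was 3066 in a separate fit to these 9 libraries, with their own gene filter, scaling and spread, and 6096 without EZH2nHom kainate replicate 2. The balance of directions turned without that library, to 2994 higher and 3102 lower, and with a correction for GC content and length, to 2366 higher and 3098 lower.

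Whether the same genes moved in both genotypes was asked of the 2 kainate responses, which share no library. In all, 1569 genes rose in both, against 260 for independent lists of these sizes, 311 fell in both, against 58.3, and 2 passed in opposite directions. Of the genes that rose in WT, 86.2% also rose in EZH2nHom, and of those that fell 62.8% also fell. Of the genes that passed as higher in EZH2nHom, 57.1% also passed as higher in WT, and of those that passed as lower 13.7% did. WT had 495 lower calls against 2266 in EZH2nHom, which caps that last share. Passing in 1 genotype alone does not show a different response, and 0 genes passed for the difference of responses. Across 11778 genes averaging over 5 CPM the log2 changes correlated with Pearson's r of 0.897 and Spearman's rho of 0.714, a description across genes, which are not independent replicates. With an adjusted p of 0.01 as the threshold, 971 genes passed in the same direction in both, and without WT kainate replicate 4 the count at 0.05 was 1233.

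**Figure D2:**
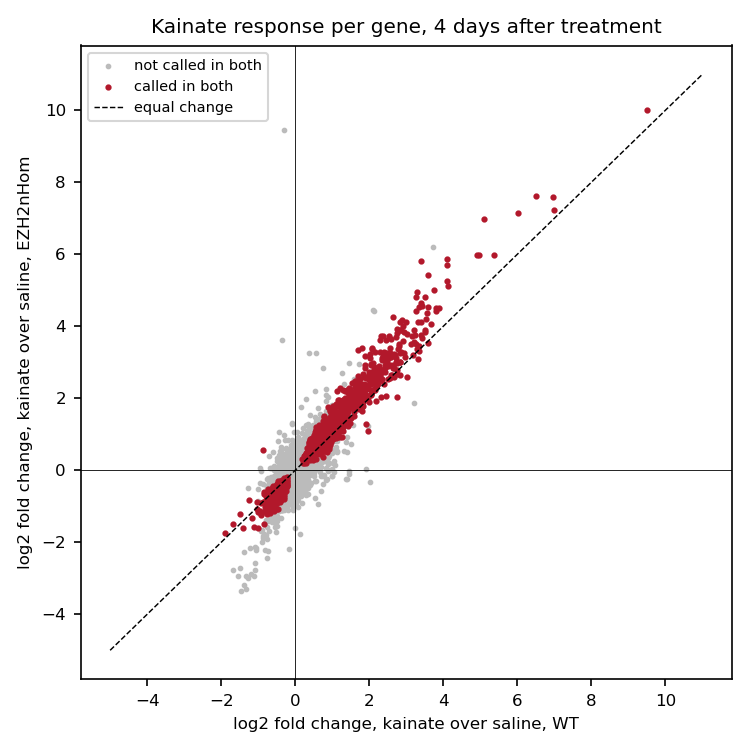
Log2 change after kainate in WT (horizontal axis) and in EZH2nHom (vertical axis), where each point is a gene with an expression above 5 CPM. The plotted genes that passed in both, 942 higher and 253 lower, lie along the rising diagonal, and the point near the vertical axis at a log2 change of 9.46 is Xist. Xist had 20611 reads in EZH2nHom kainate replicate 1 and at most 7 in its group mates.

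The size of the response was compared directly, over the 6181 genes that passed for the average of the 2 kainate responses (3414 higher, 2767 lower). The response was larger in EZH2nHom by a median of 0.208 on the log2 scale, a difference that did not pass: 3442 of 31752 relabellings of genotype within treatment gave one as large (exact two-sided permutation p = 0.108). Per library, the median response over these genes was 0.213, 0.299, 0.582, 0.676 and 0.287 in the WT kainate libraries and 0.52, 0.638, 0.525 and 0.726 in the EZH2nHom kainate libraries, so WT kainate replicates 1, 2 and 5 lay below all others. Without WT kainate replicate 4 the difference was 0.284 (exact permutation p = 0.0232), past the threshold.

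The genotype comparison after saline asks what the neuronal knockout did at baseline. Rpph1, the RNA of ribonuclease P, averaged 226 ± 88.2 CPM (SD, n = 5) in WT and 3435 ± 2776 CPM (SD, n = 5) in EZH2nHom, a log2 difference of 3.93 ± 0.66 (SE, adjusted p under edgeR = 0.000825). Scarna10, a small Cajal body RNA, averaged 108 ± 25.8 and 668 ± 113 CPM (2.62 ± 0.25, adjusted p = 3.21e-06). Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, averaged 47.3 ± 13.7 CPM in WT and 8.22 ± 0.787 CPM in EZH2nHom (-2.52 ± 0.19, adjusted p = 7e-07).

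After saline 2596 genes passed, 1603 higher and 993 lower in EZH2nHom, and 111 and 206 of these differed by 2-fold or more. Without WT saline replicate 1, 2, 3, 4 or 5, 950, 876, 822, 896 and 884 genes were higher and 1052, 873, 853, 1059 and 875 lower. The other largest rises were Rnu12 (3.22 ± 0.53), Rn7s6 (2.50 ± 0.33), Snora74a (2.26 ± 0.35), Bc1 (2.09 ± 0.43), Ndufb4c (1.52 ± 0.13), Snord17 (1.44 ± 0.31), the keratin gene Krt12 (1.40 ± 0.36) and Taf9 (1.34 ± 0.16). Of the rises, Rpph1, Rnu12, Scarna10, Rn7s6, Snora74a, Bc1 and Snord17 are small noncoding RNAs, and what raised them together was not tested. Snord94, which was lower, is one too. The other largest falls were mt-Co2 (-2.96 ± 0.46), Srp54b (-2.89 ± 0.69), Rab43 (-2.23 ± 0.30), Snord94 (-1.70 ± 0.33), Fmc1 (-1.31 ± 0.15), Rpl37rt (-1.30 ± 0.12), mt-Atp6 (-1.23 ± 0.14), Eif4ebp2 (-1.12 ± 0.13) and Atp5e (-1.10 ± 0.12). Most of these names are uncertain as counts, because their models share sequence or exonic bases with other genes: at least 20% of the 32-base words of Rnu12, Scarna10, Rn7s6, Snora74a, Bc1, Ndufb4c, Taf9, mt-Co2, Srp54b, Rab43, Rpl37rt and mt-Atp6 occur in another gene model, and Rpph1 and Snord94 share exonic bases with another gene. Among the falls, Lars2 (0.6% of words shared), Fmc1 (0%), Eif4ebp2 (0%) and Atp5e (0%) do not, nor do Snord17 (0%) and Krt12 (0%) among the rises. That check covers annotated gene models only, and reads from sequence outside the annotation were not tested, so these counts are not shown to be free of them.

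Of the gene lists 1 was higher and 1 lower after saline by camera with a preset correlation, and 0 with an estimated correlation. Of 13 mitochondrially encoded genes 6 were higher, 2 lower and 5 did not pass (6 higher and 3 lower adjusted over the list alone; adjusted p = 0.024, or adjusted p = 1 with an estimated correlation), with the complex I gene mt-Nd1 at 1.14 ± 0.13 and mt-Cytb at 0.92 ± 0.10 against mt-Atp6 at -1.23 ± 0.14. This list was not called without WT saline replicate 2 or 5 or EZH2nHom saline replicate 1, where its mean log2 difference turned from 0.045 to -0.022, -0.032 and -0.039. Of 20 astrocyte genes 7 were lower and 13 did not pass (8 lower adjusted over the list alone; adjusted p = 0.016, or adjusted p = 1 with an estimated correlation), with the potassium channel gene Kcnj10 at -0.91 ± 0.18 and the glutamate transporter gene Slc1a2 at -0.52 ± 0.13. Of 40 cytosolic ribosomal protein genes 7 were higher, 10 lower and 23 did not pass, and the list was not called (11 higher and 12 lower adjusted over the list alone; adjusted p = 1 with an estimated correlation). None of the 13 genes of PRC2 and its partners passed (0 adjusted over the list alone; adjusted p = 1 with an estimated correlation). Of the 15 measured Polycomb-silenced factors Bcl2l11 was lower (-0.53 ± 0.16) and 14 did not pass (0 adjusted over the list alone, adjusted p = 1 with an estimated correlation). These 15 are the factors that passed the filter on low counts, so the list does not speak for the rest of the 91. None of the reactive astrocyte (37), activated microglia (30), complement (20) and interferon (31) genes passed. 7SL, 7SK and mitochondrial ribosomal RNA together took 12.1 ± 0.7% of reads (SD, n = 5) in WT saline and 20.3 ± 2.6% (SD, n = 5) in EZH2nHom saline. The parts went opposite ways. In WT saline and EZH2nHom saline 7SL took 4.07 to 5.51% and 9.96 to 17.15%, and 7SK 0.66 to 0.98% and 2.10 to 3.18%. Mitochondrial ribosomal RNA took 6.2 to 7.4% and 4.02 to 5.3%. The sample codes of the genotypes share 0 prefixes, so genotype and whatever the prefixes stand for cannot be told apart. The count was 950 with the structural RNA share as a covariate, 5604 in a separate fit to the 10 saline libraries, and 1675 without WT saline replicate 3. Sex-linked reads were uneven between the 2 groups, so genotype is partly confounded with them. With a covariate from Y-linked genes the count was 2030, and 72.7% of the 2596 genes passed again in the same direction.

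The genotype comparison after kainate asks how the hippocampus of knockout mice differed from that of WT mice 4 days after seizures. The haemoglobin gene Hbb-bt averaged 124 ± 85.9 CPM (SD, n = 5) in WT and 21.6 ± 15.03 CPM (SD, n = 4) in EZH2nHom (-2.51 ± 0.60 on the log2 scale, SE, adjusted p under edgeR = 0.0194). Alas2, the haem synthesis enzyme of red cells, averaged 21.1 ± 12.9 and 5.15 ± 3.27 CPM (-2.02 ± 0.48, adjusted p = 0.0181). The stress-response gene Nupr1 averaged 12.3 ± 7.33 CPM in WT and 52.1 ± 36.5 CPM in EZH2nHom (2.08 ± 0.41, adjusted p = 0.00637). The mu opioid receptor gene Oprm1 was lower (-1.09 ± 0.23).

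After kainate 1463 genes passed between the genotypes, 878 higher and 585 lower in EZH2nHom, and 126 and 59 of these differed by 2-fold or more. These calls rest on the spread shared by all 19 libraries. A separate fit to the kainate libraries called 4 genes, whereas after saline such a fit called more genes (5604 against 2596). The gene p-values given for this comparison depend on that choice. On the leading principal component the kainate libraries lay further apart (-2.8 to 85.2) than the saline libraries (-47.1 to -38.3). The shared spread is then likely too narrow for the kainate libraries. The gene p-values of this comparison, those of Hbb-bt, Alas2 and Nupr1 included, are likely too small. The other largest rises were Rnu12 (2.31 ± 0.52), Scarna10 (1.72 ± 0.26), Col27a1 (1.54 ± 0.31), S100a4 (1.52 ± 0.39), Rn7s6 (1.39 ± 0.32), Zc3h11a (1.11 ± 0.32), Taf9 (1.09 ± 0.16), Hmgn3 (1.06 ± 0.16) and Gnl3 (1.06 ± 0.28). Gnl3 (38.09 ± 30.5 CPM, SD) and Col27a1 (14.19 ± 11.13) varied widely in EZH2nHom kainate, against 18.27 ± 0.80 and 4.86 ± 1.02 CPM in WT kainate. The other largest falls were Hba-a2 (-2.05 ± 0.49), Hbb-bs (-2.01 ± 0.47), Hba-a1 (-1.95 ± 0.51), mt-Co2 (-1.68 ± 0.47), Rab43 (-1.65 ± 0.31), Lars2 (-1.10 ± 0.20) and Romo1 (-1.02 ± 0.23). The haemoglobin genes share 59.4 to 90.8% of their words with other genes, and Rnu12, Scarna10, S100a4, Rn7s6, Zc3h11a, Taf9, mt-Co2 and Rab43 share sequence as well and Gnl3 exonic bases, so these counts are uncertain, whereas Alas2, Nupr1, Col27a1, Hmgn3 and Oprm1 share 0 to 1.4%. Of the genes that passed after saline, 566 were higher and 287 lower after kainate too, against 73.2 and 30.2 for independent lists, and 0 passed in opposite directions.

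By camera with a preset correlation 10 lists were higher and 7 lower in EZH2nHom after kainate, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.77. Of 31 type I interferon genes 7 were higher and 24 did not pass (20 higher adjusted over the list alone, adjusted p = 7e-11, or adjusted p = 0.77 with an estimated correlation), with Gbp2 at 1.42 ± 0.38. The mean log2 CPM of these genes was 2.29, 2.8, 4.07, 4.63 and 2.92 in the WT kainate libraries. It was 4.71, 3.27, 4.23 and 5.58 in the EZH2nHom kainate libraries, so the groups overlapped. Antigen presentation had 4 of 21 genes higher (11 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation), with B2m at 1.16 ± 0.29. Reactive astrocytes had 5 of 37 higher (8 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). All 6 red blood cell genes that passed, of 7, were lower (7 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation). Their mean log2 CPM was 6.36, 4.18, 5.87, 4.48 and 4.1 in the WT kainate libraries and 1.48 to 3.62 in EZH2nHom kainate. Of 36 glutamate and GABA receptor genes 4 were lower (6 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation), with Gabra2 at -1.18 ± 0.34. Of 22 inhibitory neuron genes 4 were lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). None of the 22 myelin genes passed, though the list was called lower (0 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation), but not without EZH2nHom kainate replicate 2 (adjusted p = 0.0596). Neither the PRC2 list (0 of 13 genes passed, 0 adjusted over the list alone; adjusted p = 0.8 with an estimated correlation) nor the Polycomb-silenced factors (0 of 15, 0 adjusted over the list alone; adjusted p = 0.87 with an estimated correlation) was called. Structural RNA took 15.3 ± 2.9% of reads (SD, n = 5) in WT kainate and 20.4 ± 5.6% (SD, n = 4) in EZH2nHom kainate. The count moved with the choices made: it was 4 in a separate fit to these 9 libraries, 4 higher and 0 lower (edgeR; 2601 at an unadjusted p under 0.05), where Hbb-bt, Alas2, Nupr1 and Oprm1 no longer passed, 924 with a correction for GC content and length, 959 without a filter on low counts and 2224 in DESeq2. It was 670, 706 and 947 without WT kainate replicate 2, 1 or 5, and 1315 without EZH2nHom kainate replicate 2. With a covariate from Y-linked genes it was 1195, and 80% of the 1463 genes passed again in the same direction.

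Whether kainate acted differently in the 2 genotypes was tested as the difference of the responses. No single gene passed: edgeR called 0 of 19234 genes (smallest adjusted p = 0.13), 1685 had an unadjusted p under 0.05 against 962 by chance, and DESeq2 called 14. The genes nearest the threshold were Tomm6 (-0.64 ± 0.11, adjusted p = 0.128), of the mitochondrial import pore, and Ctr9 (-0.51 ± 0.09, adjusted p = 0.128), both chosen after their values were seen. Lists of genes did differ with a preset correlation, 13 with a positive and 11 with a negative difference (EZH2nHom minus WT), and 0 with an estimated correlation, where the smallest adjusted p was 0.57. Of these 24 lists 9 were called whichever library was left out, and 15 were lost without at least 1 library. The response of the 31 interferon genes was larger by a mean of 1.06 on the log2 scale (0 adjusted over the list alone; adjusted p = 4.2e-13, or adjusted p = 0.57 with an estimated correlation). It was larger for the 21 antigen presentation genes by 0.86 (1 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). It was larger by 0.84 for the 37 reactive astrocyte genes (0 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). The 7 red blood cell genes, which rose in WT, had a mean difference of -1.81 (4 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). Their rise was uneven, as only WT kainate replicates 1 and 3 (mean log2 CPM 6.36 and 5.87) lay above WT saline (2.85 to 4.53). The 22 myelin genes had a mean difference of -0.53 (0 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), or -0.32 without EZH2nHom kainate replicate 2 (adjusted p = 0.00204). Ezh2 itself had a difference of -0.06 ± 0.23 (adjusted p = 0.948). The PRC2 list had a mean of 0.1 (0 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). The 15 Polycomb-silenced factors had a mean of -0.12 (1 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). In simulated data with these library sizes the test recovered 14.8% of 1.5-fold, 65.2% of 2-fold and 87.9% of 4-fold differences of response. Leaving out WT saline replicate 1, EZH2nHom saline replicate 5 or EZH2nHom kainate replicate 2 gave 1, 1 and 4 genes.

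**Figure D3:**
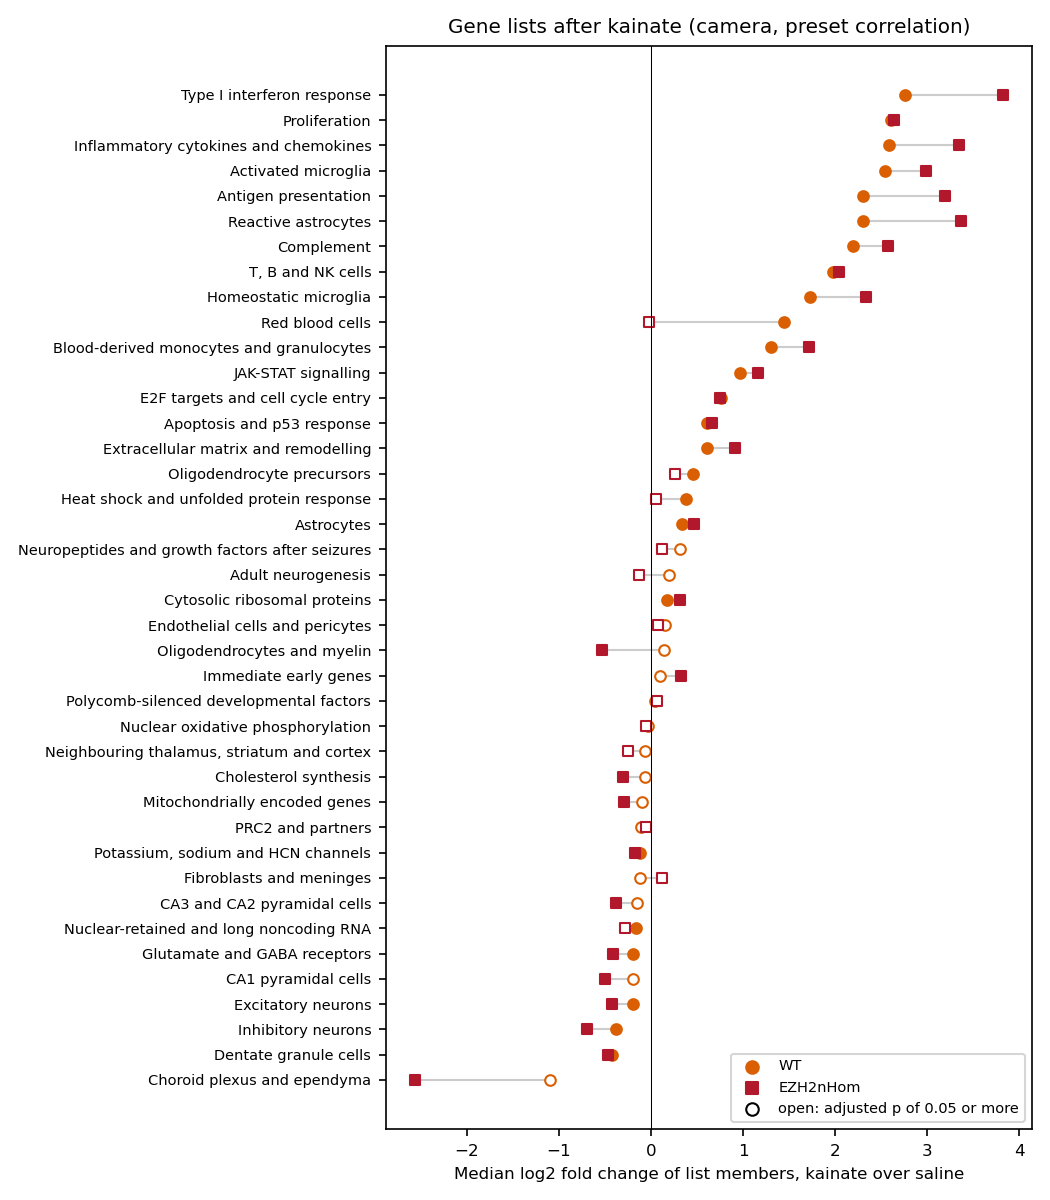
Median log2 change after kainate of the measured genes of each gene list, in WT and in EZH2nHom. The interferon list lay at 2.76 in WT and 3.82 in EZH2nHom, and the inhibitory neuron list at -0.38 and -0.69.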

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

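The tests of EZH2nHom kainate replicate 2 (depth and most-read genes, structural and mitochondrial RNA, glucocorticoid-induced genes) and the test of shared reads among genes at 2-fold or more were chosen only after the result was seen.

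Between the genotypes after saline 2596 genes passed, while 99 other drawn splits of the 10 saline libraries gave at most 0. This argues against chance, to the resolution of the splits drawn. The real split also parts the code prefixes, so the splits do not single out genotype. GC content and length as the whole cause were argued against by the correction, after which 74% of these genes passed again in the same direction. Reads shared with another gene model were a property of 19.1% of these genes, against 15.5% of all genes tested. Its 95% counting interval, 17.6 to 20.6%, reached the bound of 20% but lay far under 50%, which argues against shared reads as the whole cause, but among genes at 2-fold or more the share was 37.7% and shared reads may account for part. A library difference that goes with structural RNA cannot be told apart from genotype, nor can whatever the code prefixes stand for (0 shared). The slopes on the structural RNA share within groups correlated with the genotype change at r = 0.174, above 83.6% of 1000 shuffles. With that share as a covariate 950 genes passed. A difference in alignment or annotation between the genotypes was not tested either. Gm49337, for example, had 0 reads in WT saline and 26 to 216 in EZH2nHom saline. Sex-linked reads were uneven between the genotypes as well, and 2030 genes passed with a covariate from Y-linked genes. The loss of neuronal EZH2 stays open as untested.

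EZH2nHom kainate replicate 2 had 353 genes at least 2-fold above and 978 at least 2-fold below all its group mates, against at most 53 and 51 in any other library. Gpr17, a receptor of oligodendrocyte precursors, was at 2.8 CPM against 234.7 to 332.1, the microglial receptor gene Cx3cr1 at 26 against 118.2 to 178.1, and the kinase gene Sgk1 at 494.2 against 60.4 to 75.7. Depth or a few dominant genes was argued against, since 0 of 2 measures lay outside the other 18 libraries (29778706 reads, and 22.99% of them on the 10 most read genes), and so was a larger share of structural RNA or mitochondrial reads, with 0 of 2 measures outside (17.11% and 3.17%). Glucocorticoid-induced genes, from a longer list narrowed to those not among the genes first noticed, were higher by a mean of 1.71 on the log2 scale, all 11 of 11, against -0.26 to 0.23 in the libraries of the other groups, so a stress-hormone response in that animal is a candidate explanation, found and tested on the same data. Ccn2 (328.8 CPM against 12.4 to 19), Igfbp3 (130.3 against 13 to 20.3), Rbm3 (414.2 against 55.1 to 108) and Cirbp (79.7 against 17.2 to 33.4) were higher in that library too. What raised them was not tested. No group of the design separates this animal from the others, and no other biological explanation was tested.

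Between the genotypes after kainate 1463 genes passed, but 6 of 100 splits of the 9 kainate libraries gave as many and the highest other gave 2418, so chance could not be excluded for this count. That split set WT kainate replicates 3 and 4 with EZH2nHom kainate replicates 1 and 4. These libraries had the highest mean log2 CPM of activated microglia genes among the kainate libraries (4.89 to 5.78, others 3.36 to 4.55). They were also highest for homeostatic microglia genes (6.52 to 7.07, others 5.45 to 6.17), both lists chosen after the values were seen. Whether this difference between animals raised the count was not tested. Of the 1463 genes, 566 were higher and 287 lower after saline too, in other libraries, against 73.2 and 30.2 for independent lists, with 0 in opposite directions. This argues against chance for those genes, not for the rest, and does not part genotype from the code prefixes. For the kainate response 1 of 100 splits, the real one, gave as many genes in WT (2316, highest other 738) and 1 of 100 in EZH2nHom (5012, highest other 2546). This argues against chance in both, to the resolution of 100 splits. In WT the libraries of shared code prefixes called 0 genes with the prefix as a block (edgeR, 2167 at an unadjusted p under 0.05). These are only saline replicates 2 and 4 and kainate replicates 1 to 4. So few libraries leave little power, so this count of 0 decides nothing. Among the 16 splits that part all same-numbered WT libraries the highest other was 0, but 1 of 16 is the smallest share attainable, which is too coarse to decide. For the difference of responses, where 0 genes passed in edgeR (1685 at an unadjusted p under 0.05, 14 in DESeq2), the 100 regroupings decide nothing about chance, because all 100 give as many as 0. The highest other gave 548, and what raised that count was not tested.

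A library lay far from its group mates in 19 of 258 sets tested, where chance gives about 5%, and 4 of the 19 were in EZH2nHom kainate replicate 2. In that library the mean log2 CPM of oligodendrocyte precursor genes was 4.46 (others 5.47 to 5.58) and of CA3 and CA2 genes 4.2 (4.36 to 4.39), Saa3 was at 32.7 CPM (0.21 to 1.32) and Lars2 at 8.07 CPM (13.21 to 13.9). In EZH2nHom kainate replicate 1 the mean log2 CPM of heat shock genes was 5.33 (5.46 to 5.48) and of sex-linked genes -1.28 (2.69 to 3.33), and Rtl3 was at 0.603 CPM (0.23 to 0.26). In its group only that library had high Xist (20611 reads) and Y-linked genes at or near 0. In EZH2nHom kainate replicate 4 Rpph1 was at 6910 CPM (1089.18 to 1860.06). In EZH2nHom saline replicate 5 the mean log2 CPM of astrocyte genes was 6.85 (6.9 to 6.92) and of neuropeptide and growth factor genes 3.76 (2.97 to 3.05), Saa3 was at 0.0297 CPM (0 in the others) and Irs4 at 5.17 CPM (0.73 to 1.95). In EZH2nHom saline replicate 4 the homeostatic microglia genes were at 4.3 (4.42 to 4.46), and in replicate 3 mt-Co2 was at 38.4 CPM (4.41 to 13.43). In WT saline replicate 3 Hbb-bt was at 62.3 CPM (21.85 to 33.49), Hba-a2 at 142 CPM (43.15 to 63.55) and the blood monocyte and granulocyte genes at a mean log2 CPM of 0.58 (0.09 to 0.2). In WT kainate replicate 3 the immediate early genes were at 3.52 (3 to 3.09), and in WT kainate replicate 4 Saa3 was at 5.53 CPM (0.06 to 1.52).

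For 24 lists camera with a preset correlation found a difference between the kainate responses, which 0 kept with an estimated correlation (smallest adjusted p = 0.57), and 15 of the 24 were lost without at least 1 library. The 9 kept throughout, with the preset correlation only, were JAK-STAT signalling, type I interferon, reactive astrocytes, antigen presentation, oligodendrocytes and myelin, red blood cells, CA3 and CA2, adult neurogenesis and glutamate and GABA receptors. The mean difference, EZH2nHom minus WT, was positive for JAK-STAT signalling (0.35 on the log2 scale), inflammatory cytokines (0.75), complement (0.42), type I interferon (1.06), homeostatic microglia (0.31), activated microglia (0.37), astrocytes (0.15), reactive astrocytes (0.84), blood monocytes and granulocytes (0.51), extracellular matrix (0.27), antigen presentation (0.86), apoptosis and the p53 response (0.3) and ribosomal proteins (0.14). It was negative for oligodendrocytes and myelin (-0.53), choroid plexus and ependyma (-1.21), red blood cells (-1.81), inhibitory neurons (-0.23), CA1 (-0.4), CA3 and CA2 (-0.29), neighbouring thalamus, striatum and cortex (-0.29), adult neurogenesis (-0.44), glutamate and GABA receptors (-0.23), cholesterol synthesis (-0.17) and heat shock (-0.14). The mean of extracellular matrix turned to -0.044 without EZH2nHom kainate replicate 2 and that of heat shock to 0.03 without WT kainate replicate 3. Cholesterol synthesis was at -0.03 without EZH2nHom kainate replicate 1, and without replicate 4 homeostatic microglia were at 0.038 and activated microglia at 0.11. Without EZH2nHom kainate replicate 4 complement was at 0.186 and inflammatory cytokines at 0.49. Without EZH2nHom kainate replicate 2 blood monocytes and granulocytes were at 0.235, apoptosis and the p53 response at 0.148 and ribosomal proteins at 0.059. CA1 was at -0.244 without WT kainate replicate 1.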

How the results depend on the processing

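The structural RNA covariate, the GC and length correction and the size test in libraries with Y-linked reads were tests chosen only after the results were seen. Over all alternatives, named genes kept their direction and side of the threshold in 15484 cases, lost it in 1122, gained it in 284 and reversed in 0. Lists kept theirs in 2683 cases, lost it in 196, gained it in 72 and reversed in 1. The reversal was the nuclear oxidative phosphorylation list in the difference of responses, at a mean of 0.097 without EZH2nHom kainate replicate 1. The cause of the shifts below was not tested unless fewer libraries or genes give it. Genes that passed in WT after kainate numbered 0 in the 6 libraries of shared prefixes, which leave little power (edgeR, 2167 at an unadjusted p under 0.05). They numbered 933 with the structural RNA covariate and 1365 to 2675 without 1 library. In EZH2nHom they numbered 3066 in a fit to the groups compared and 3864 to 6096 without 1 library. The correction for GC content and length moved the share of higher genes from 78.6 to 67.2% in WT and from 54.8 to 43.3% in EZH2nHom. Between the genotypes after saline they numbered 950 with the structural RNA covariate, 5604 in a fit to the groups compared and 1675 to 2385 without 1 library, with 45.8 to 50.3% higher without a WT saline library against 61.7% with all. After kainate they numbered 959 without a filter, 924 with the GC and length correction, 2224 in DESeq2, 4 in a fit to the groups compared and 670 to 2193 without 1 library. For the difference of responses they numbered 14 in DESeq2 and 0 to 4 without 1 library.

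With an estimated correlation 0 lists passed in any of the 5 contrasts. Lists called whichever library was left out numbered 23 of 25 for kainate in WT, 24 of 28 in EZH2nHom, 1 of 2 for genotype after saline, 7 of 17 after kainate and 9 of 24 for the difference. Without 1 library the lists that passed numbered 24 to 29 for kainate in WT, 26 to 29 in EZH2nHom, 1 to 3 for genotype after saline (1 without WT saline replicate 2 or 5 or EZH2nHom saline replicate 1), 11 to 23 after kainate (11 without WT kainate replicate 1) and 14 to 28 for the difference (14 without EZH2nHom kainate replicate 4). Over all alternatives the kainate change of Ezh2 ran from 0.235 to 0.511 in WT (0.302 to 0.511 without 1 library), passing at 0.511 and 0.504 without WT kainate replicate 1 or 5, and from 0.305 to 0.446 in EZH2nHom, where it passed in a fit to the groups compared (0.421, adjusted p = 0.0476). Its genotype difference ran from 0.052 to 0.319 after saline and 0.096 to 0.339 after kainate, lowest in both with the structural RNA covariate, and its difference of responses from -0.136 to 0.101. The overlap of the kainate responses was 971 genes at an adjusted p of 0.01 and 1233 to 2598 without 1 library. The size difference ran from 0.142 to 0.284 without 1 library, passing without WT kainate replicate 4, and was 0.132 (exact permutation p = 0.393) in libraries with Y-linked reads.

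Replicate numbers were not taken to pair the libraries outside WT: the correlations ran from -0.035 to 0.19 for kainate in EZH2nHom (1 of 4 matched best with its own number), 0.073 to 0.565 for genotype after saline (2 of 5) and -0.062 to 0.524 after kainate (2 of 4). With the replicate block the counts were 2477 in WT and 5023 in EZH2nHom after kainate, 2809 and 1191 between genotypes after saline and kainate, and 0 for the difference (1809 at an unadjusted p under 0.05), with 25, 29, 2, 16 and 25 lists. Of the named genes it lost 4 and gained 6 calls in WT, lost 5 and gained 4 in EZH2nHom, lost 3 and gained 12 after saline, lost 18 and gained 7 after kainate and changed 0 for the difference. Of the lists it gained 1 in EZH2nHom, lost 1 after kainate, and gained 2 and lost 1 for the difference.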

Other observations

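The look at overlapping gene models and at the genes around Ezh2 used tests chosen only after the results were seen. Of 27 inflammatory cytokine and chemokine genes 17 rose in WT, 1 fell and 9 did not pass (20 rose and 1 fell adjusted over the list alone; adjusted p = 0.089 with an estimated correlation), with Ccl3 at 4.28 ± 0.59 and Ccl12 at 4.47 ± 0.66 on the log2 scale (SE). In EZH2nHom 22 rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 0.073 with an estimated correlation), and Ccl5, with 0 reads in EZH2nHom saline, was at least 16.7-fold higher. Of 39 extracellular matrix genes 13 rose in WT (17 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), with the thrombospondin gene Thbs4 at 2.19 ± 0.24. In EZH2nHom 24 rose and 2 fell (24 and 2 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Of 27 E2F target and cell cycle entry genes 14 rose in WT (18 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with E2f8 at 2.83 ± 0.39. In EZH2nHom 14 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). Of 34 potassium, sodium and HCN channel genes 3 fell and 1 rose in WT (3 and 1 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), and the list was not called without WT kainate replicate 4 (adjusted p = 0.156). In EZH2nHom 10 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation), with the sodium channel subunit gene Scn3b at -1.19 ± 0.20. None of the 20 choroid plexus and ependyma genes passed in EZH2nHom, though the list was called lower (0 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation), but not without EZH2nHom kainate replicate 2 (adjusted p = 0.0761). The mean log2 change of the list was -1.85 without that library and -2.125 with it.

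Some predicted gene models were read almost only in EZH2nHom libraries. Gm49369, which overlaps the cathepsin gene Ctsd, had 0 reads in all 5 WT saline libraries and 254 to 1012 in EZH2nHom saline, at least 209-fold higher against a floor of 3 reads per library, and 0 to 5 reads in WT kainate against 1597 to 3925 in EZH2nHom kainate. Gm49337 had 0 reads in all 10 WT libraries and was at least 39.6-fold higher after saline and at least 21.7-fold higher after kainate. Gm49450, which overlaps the tubulin genes Tuba1a and Tuba1b, had 0 to 24 reads in WT saline and 852 to 2944 in EZH2nHom saline. The deposited files do not state whether both genotypes were aligned to the same annotation, and these folds hold only if they were. The genotype comparisons rest on the same condition. Ctsd did not pass after saline (-0.16 ± 0.33, adjusted p under edgeR = 0.808), while Tuba1a (0.62 ± 0.08, adjusted p = 4.27e-05) and Tuba1b (0.30 ± 0.06, adjusted p = 0.00375) were higher in EZH2nHom after saline. After kainate neither passed (Tuba1a 0.11 ± 0.08, adjusted p = 0.439, and Tuba1b adjusted p = 0.993), nor did Ctsd (0.24 ± 0.34, adjusted p = 0.723). Of the 100 tested genes nearest to Ezh2, 6 passed between the genotypes after saline and 2 after kainate, or 6% and 2%, against 13.5% and 7.6% of all genes.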
